A study of Mus musculus and Homo sapiens with 25 samples.

How the data were processed

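The series measured circular RNAs (circRNAs) by RNA sequencing in 25 libraries. Circular RNAs were called from reads that span a back-splice, the join of a downstream splice donor to an upstream acceptor. RNA was extracted with TRIZOL, depleted of ribosomal RNA and made into TruSeq libraries per the labels. The 19 mouse libraries came from P19 embryonic carcinoma cells, brain lysate, synaptoneurosomes, cytoplasm, cultured cortical neurons and 4 dissected brain regions. The other 6 libraries came from the human neuroblastoma line SH-SY5Y. The P19 and fraction libraries were run on a HiSeq2000 and the others on a HiSeq2500 per the labels.

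Each deposited list holds 1 line per circRNA with its chromosome, start, end, strand and a last value read here as the count of junction reads. That reading rests on the values, which are whole numbers of 2 or more, and every share and interval depends on it. The authors used CASAVA 1.8.2 and Bowtie2 and the genome builds mm9 and hg19 per the submitters' processing notes. The circRNA caller and its filters are not given in the sources used here. Every listed circRNA had at least 2 reads and a span from 101 bases to under 100 kb, so a circRNA missing from a list had fewer than 2 reads or had been filtered out. It was counted as 0 in that library, and 1 read in its place was tried as an alternative. The total of a list is the sum of its junction reads and not the depth of its library, which was not given in the sources used here. All shares below are percentages of that total.

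A circRNA was defined by chromosome, start, end and strand. Its ends were matched to exon boundaries on its own strand in gencode vM1 for mouse and gencode v44lift37 for human. Classes were both ends in 1 gene, ends in 2 genes, 1 end, inside a gene, and none of these, the last written below as "no gene". Cdr1as was matched by its position antisense to Cdr1, never by the symbol of its host. Junctions were also searched for a sequence copy, a stretch of 25 bases with at most 2 mismatches within 50 kb of the other end, placed where linear splicing within 1 gene copy would give the same join. Ends with 10 or more exact copies of their 25 bases in the genome were counted as repeated. This last search, and the leaving out of junctions with a copy or without both ends in 1 gene, were chosen after the values were seen.

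P19 days 4 and 12 were compared with day 0, and day 12 with day 4, and SH-SY5Y day 4 with day 0, with 2 libraries per day. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, a mean for each day, and all libraries of the cell line in 1 fit. Days with 1 library entered the fit but got no p. A circRNA was tested if listed in at least 2 libraries with at least 10 reads over them, and called at a Benjamini-Hochberg adjusted p under 0.05. Spread came from the few pairs of libraries of the same day. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so none was run.

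Host genes were grouped in 16 lists, and lists with at least 5 tested circRNAs were tested with camera of limma 3.58.1 on log2-CPM values (prior count 2) with a preset correlation of 0.01, with p adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, which asks whether the members of a list move on balance 1 way, were run as alternatives. Fry tests against 0 and so also takes in any shift of all circRNAs. One list gathers hosts named in work on brain circRNAs and was drawn partly from this study's paper, so it is not independent evidence.

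Regions, neuron days and fractions had 1 library each and were not tested. For these the share of a circRNA was compared as a ratio with its exact 95% conditional binomial (Clopper-Pearson) interval, over circRNAs with at least 20 reads in the set. A ratio against 0 reads was taken against a floor of 3 counts over the group and is given as a bound. The exact limit beside it takes an unlisted circRNA as 0 reads. A list can lack a single read, so that limit can lie too high. Median log2 ratios of a list were ranked among 10000 random lists of the same size drawn from 10 bins of abundance. Numbers of circRNAs were also counted after each library was thinned 100 times to the lowest total of its set. A corrected thinning, drawn until the reads of circRNAs with 2 or more came to that total, was added after the data were seen. So were the comparisons of regions without the cerebellum.

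Before the data were examined the comparisons, lists, tests and most alternatives were fixed, as was the rule for named genes. It takes up to 10 circRNAs higher and 10 lower among those past the test whose days do not overlap, 5 per region, 8 in each direction for neurons, 10 in each direction for fractions, the 5 with the highest mean share in each set, and up to 4 members per list. It always takes the most abundant circRNA of 13 hosts known from work on brain circRNAs, including this study's paper. Ratios and bounds on the list totals, given beside the scaled ones of the tests, were added after the data were seen. Any other circRNA named below was chosen after its values were seen, and the text says so.

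Alternatives were the size factors of DESeq2 1.42.0 within edgeR, DESeq2 itself, TMMwsp and no scaling, no filter, at least 5 reads in 2 libraries, only the libraries of the days compared, each library left out in turn, counts summed per host gene, TMM-scaled totals and a minimum of 50 reads for the untested sets, and positions matched within 5 bases. An experiment number was also fitted as a replicate block. In SH-SY5Y it stands in the labels. In P19 only the second series is labelled, as experiment 2, and the first was assumed to be experiment 1, so the pairing of its days rests on that assumption. The correlation of the deviations of paired libraries was 0.0315 for P19 days 0 and 12, 0.0478 for days 0 and 4, 0.0065 for days 4 and 12, and 0.182 for SH-SY5Y days 0 and 4, and the fit without the block is the one reported.

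The steps were tested on simulated data. With the spread of these libraries (a common dispersion of 0.407 in P19 and 0.405 in SH-SY5Y), the test recovered 0.3% of 4-fold and 12.4% of 16-fold changes in P19, and 2.8% and 11.4% in SH-SY5Y, with 0 false calls in 5 runs. At a dispersion of 0.05 it recovered 25.2% and 62.1% in P19. The exact intervals covered the simulated ratio in 96.2% of 4000 draws. With no change simulated, 1 of 20 P19 runs of day 12 against day 0 gave 1 call. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. No listed column was left unassigned. The reads themselves, linear RNA levels and the ratio of circular to linear RNA were not analysed here.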

Results

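Junction reads of circRNAs were counted in 25 libraries that fall into 5 sets. P19 cells, a mouse embryonic carcinoma line that turns into neurons with retinoic acid (1 µM), were sampled undifferentiated on day 0 (n = 2), as embryoid bodies on days 2 (n = 1) and 4 (n = 2), and after plating on day 12 (n = 2). SH-SY5Y cells, a human neuroblastoma line given the same dose of retinoic acid, were sampled on days 0 (n = 2), 2 (n = 1), 4 (n = 2) and 8 (n = 1). Mouse cortical neurons in culture (days 1, 7, 14, 21 and 28), regions of mouse brain (olfactory bulb, prefrontal cortex, hippocampus and cerebellum) and brain fractions (lysate, synaptoneurosomes, which are pinched-off synapses, and cytoplasm) had 1 library each. The labels mark replicates 1 and 2 of an SH-SY5Y day as separate experiments. In P19 they mark replicate 2 as a second experiment and give replicate 1 no number, so it was assumed to be a first one. Junction reads per library ranged from 1222 to 5319 in P19, 1583 to 9182 in SH-SY5Y, 6910 to 14588 in neurons, 5022 to 14267 in regions and 2974 to 4747 in fractions. These are sums of the listed reads and not sequencing depths.

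The mouse lists held 8649 distinct circRNAs with 118959 reads and the human lists 4264 with 28756 reads. In mouse, 77.3% had both ends at exon boundaries of 1 gene, and 81.5% in human. They came from 2869 mouse and 1985 human host genes, and 51.9% of the human hosts shared their symbol with a mouse host. Nbea, which codes for neurobeachin, a protein of membrane trafficking, gave the most mouse circRNAs (24), followed by Dgki (21) and Anks1b (18). In human EML5 (15), UBAP2 (13) and PTK2 (12), the gene of focal adhesion kinase, led. The circles started at exon 2 in 28.1% of mouse and 28.5% of human cases and at exon 1 in 0.2% of each. Their median was 4 exons and 527.5 exonic bases in mouse, and 3 exons and 470 bases in human. Only coding exons were enclosed in 85.5% and 83.5%. All searched junctions were flanked by AG and by GT or GC. Junctions whose ends lay in 2 genes numbered 29 in mouse and 23 in human, and 75.0% of these 52 had a sequence copy from which linear splicing would give the same join. Of 10164 circRNAs within 1 gene, 0.098% had one.

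The numbers of circRNAs per library followed the junction reads. P19 libraries held 360 ± 83.4 (SD, n = 2) circRNAs on day 0, 837 ± 411.5 on day 4 and 1000 ± 297 on day 12. SH-SY5Y libraries held 1470 ± 985 on day 0 and 1010 ± 410 on day 4. Neurons held 1464 circRNAs on day 1, 1949 on day 7, 2717 on day 14, 2558 on day 21 and 1638 on day 28. Among the regions the cerebellum held 2407, the prefrontal cortex 1771, the hippocampus 1677 and the olfactory bulb 1212. Synaptoneurosomes held 1117, the lysate 847 and the cytoplasm 709. The ratio of day 12 to day 0 in P19 was 2.78 as listed, 0.814 after thinning to equal reads, and 1.09 after the corrected thinning chosen once the data were seen. Since the lists lack single reads, the first thinning lowers the numbers of deep libraries more than those of shallow ones, so its ratios below 1 are no evidence of a reversal. For the cerebellum over the olfactory bulb these values were 1.99, 0.749 and 0.875, and for neurons on day 14 over day 1 they were 1.86, 0.926 and 1.04. For synaptoneurosomes over cytoplasm they were 1.58, 0.99 and 1.09. For SH-SY5Y day 4 over day 0 they were 0.687, 1.09 and 1.00, and the first was 1.31 without day 0 replicate 1. Identical junctions found in every library numbered 46 of 2735 in P19, 102 of 4264 in SH-SY5Y, 430 of 5267 in neurons, 390 of 4264 in regions and 270 of 1773 in fractions.

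P19 day 12 was compared with day 0 to see which circRNAs accompany neuronal differentiation. The circRNA of Rmst, a long noncoding RNA of neurogenesis (chromosome 10, 91537915 to 91599435, minus strand, 1 annotated end), had 0 reads in both day 0 libraries, 5 on day 2, 28 and 85 on day 4, and 123 and 30 on day 12. Its share was 1.65 ± 0.936% (SD, n = 2) on day 12, at least 14.95-fold higher on the list totals than a floor of 3 counts over the day 0 libraries (28.8-fold on TMM-scaled totals). With 1 library of these days left out, the bound on the list totals ran from 6.72-fold to 20.9-fold. The circRNA of Tulp4, a tubby-like gene (chromosome 17, 6137211 to 6139156), took 1.12 ± 0.31% on day 0 and 2.46 ± 0.392% on day 12, a log2 ratio of 1.14. Rims2, whose protein tethers synaptic vesicles at the active zone (chromosome 15, 39398489 to 39448056, exons 21 to 24), went from 0.149 ± 0.021% to 0.553 ± 0.197%, a log2 ratio of 1.89. The log2 fold changes of the tests are on TMM-scaled totals, which raise day 12 over day 0 in P19, and came to 1.87 (SE 0.33) for Tulp4 and 2.59 (SE 0.75) for Rims2. None of these passed the test over all 415 circRNAs, with adjusted p of 0.0773 for Rmst and Tulp4 and 0.241 for Rims2 by edgeR. Adjusted over the list alone, that is over the always reported circRNAs, the values were 0.00279, 0.00279 and 0.0319. These hosts were known in part from this study's paper, so the latter values are not independent evidence.

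By edgeR 0 of 415 circRNAs passed at day 12 against day 0, with 80 at an unadjusted p under 0.05 (52 higher and 28 lower, against a mean of 16.4 and at most 25 in libraries simulated without any change) and 8 by DESeq2 (3 higher and 5 lower). With the experiment as a replicate block, which in P19 rests on an assumed number for replicate 1, 9 passed (4 higher and 5 lower), Rmst among them with an adjusted p of 1.69e-11 and Tulp4 with 0.000409. Without scaling 17 passed (3 higher and 14 lower). Days did not overlap for 196 circRNAs (47.2%), 148 higher and 48 lower. Libraries simulated without any change, a comparison chosen after the data were seen, gave 37.1% (34.1% to 41.3% over 20 runs), on average 117 higher and 17.6 lower, so an upward split arises without a change. P-values here measure the spread between these libraries, which can be technical. Among the other circRNAs with the lowest p, chosen after their values were seen, Zfp827 had 0 and 0 reads on day 0 and 26 and 22 on day 12, at least 5.50-fold higher on the list totals (9.03-fold scaled, adjusted p = 0.114). The circRNA of Ash1l, a histone methyltransferase (chromosome 3, 88811064 to 88847565, exons 4 to 11), had 26 and 25 reads on day 0, 3 and 3 on day 4, and 5 and 0 on day 12, a log2 ratio of shares of −5.33 (scaled −4.18, SE 0.94, adjusted p = 0.207). Ddx19a, a DEAD-box RNA helicase gene, was among the 5 with the highest mean share and went from 2.53 ± 0.359% to 0.412 ± 0.023%, a log2 ratio of −2.62 (scaled −1.83, SE 0.31, adjusted p = 0.0773). Its junction has 1 annotated end and a sequence copy. The median log2 fold change of all 415 was 1.36, with 165 listed on day 12 but not on day 0. This median was 0.71 without scaling, 0.34 with unlisted circRNAs at their bound and 0.32 over those listed on both days. Simulated libraries without any change had a median of 1.09 (0.85 to 1.27 over 20 runs), and 0.28 without scaling.

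**Figure D1:**
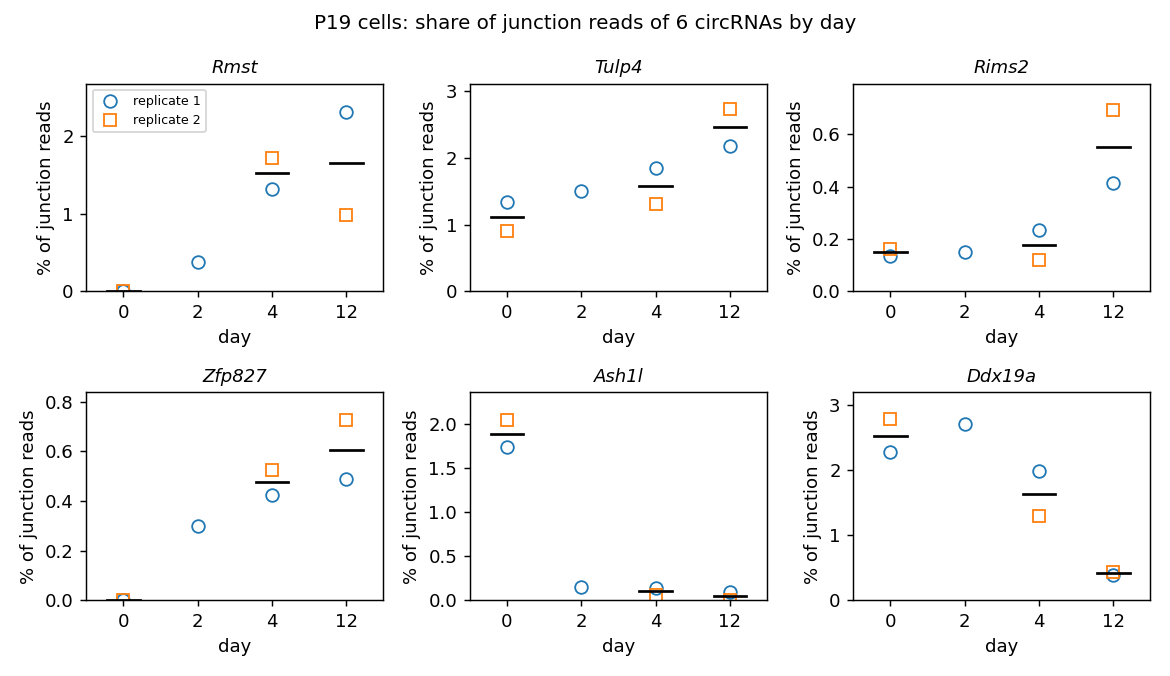
Share of junction reads (%, linear axis) of 6 P19 circRNAs by day, 1 point per library, marked by replicate. Rmst was not listed on day 0 and took 1.65% on average on day 12, whereas Ash1l had 26 and 25 reads on day 0 and 5 and 0 on day 12.

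The other always reported circRNAs did not pass in P19 either. Elf2, the gene of an ETS transcription factor, had 0 and 2 reads on day 0, 11 and 19 on day 4, and 29 and 8 on day 12. The transcription regulator Zfp609 took 0.97 ± 0.331% on day 0 and 1.08 ± 0.361% on day 12, a log2 ratio of 0.15 (scaled 0.94, SE 0.50). Hipk3, a kinase gene whose second exon forms a circle, had a log2 ratio of shares of 0.38 (scaled 1.13, SE 0.77). Kat6b (annotated as Myst4), Phf21a, Homer1 and Stau2 had at most 12 reads in any P19 library. Cdr1as was listed in 1 P19 library, day 12 replicate 2, with 2 reads, Klhl2 in 1 with 2, and Dlgap1 in none. The 5 highest mean shares also held Scd2 and Scd3, desaturase genes joined by 1 junction, with 165 reads in day 0 replicate 2 (13.5% of that library) and 0 in the other P19 libraries. A pair of junctions between the tubulin genes Tubg1 and Tubg2 took from 0.301% to 3.61%. These 3 junctions have sequence copies, and reads of such junctions came to 23.9% of day 0 replicate 2 and 1.62% of day 12 replicate 1.

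At day 4 against day 0, embryoid bodies against undifferentiated cells, Rmst was at least 13.8-fold higher on the list totals (22.5-fold scaled, adjusted p = 0.158) and Tulp4 had a log2 ratio of shares of 0.50 (scaled 1.01, SE 0.33, adjusted p = 0.398). With 1 library left out the bound of Rmst on the list totals ran from 6.19-fold to 15.6-fold. Chosen after their values were seen, Whsc1, the gene of a histone H3 methyltransferase, had 8 and 6 reads on day 0 and 33 and 57 on day 4 (log2 ratio 1.40, scaled 1.92, SE 0.45), and Zfp827 was at least 4.31-fold higher on the list totals. By edgeR 0 of 415 circRNAs passed, 39 had an unadjusted p under 0.05 (33 higher and 6 lower, against at most 25 without any change), and DESeq2 called 2. The replicate block gave 3 calls, with Rmst at an adjusted p of 9.71e-11. Leaving out day 4 replicate 1 or day 4 replicate 2 gave 1 call each, with adjusted p for Rmst of 0.000201 and 0.00423. Days did not overlap for 192 circRNAs (46.3%), 150 higher and 42 lower, against 30.5% without any change (27.4% to 33.7%), on average 90 higher and 20.8 lower.

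At day 12 against day 4 Rims2 and Tulp4 had log2 ratios of shares of 1.63 (scaled 1.87, SE 0.66) and 0.64 (scaled 0.87, SE 0.31), both with an adjusted p of 0.544. Ddx19a had −1.99 (scaled −1.73, SE 0.30, adjusted p = 0.246). Chosen after their values were seen, Aff3 (chromosome 1, 38591751 to 38595846), a transcription elongation gene, went from 0 and 0 reads to 17 and 17, at least 10.4-fold higher on the list totals. Mdk, which codes for the growth factor midkine, and the homeobox gene Hoxb3 were at least 9.01-fold and 6.48-fold lower on the list totals (7.06-fold and 5.30-fold scaled), each with 1 annotated end. The other 8 always reported circRNAs tested had log2 fold changes smaller than their SEs. By edgeR 0 of 415 passed, with 35 at an unadjusted p under 0.05 (14 higher and 21 lower, against at most 14 without any change), 0 by DESeq2 and 5 with the replicate block. Days did not overlap for 162 (39.0%), 71 higher and 91 lower, against 30.5% without any change (24.6% to 35%).

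Of the host gene lists, 5 had enough circRNAs in P19. The list named in work on brain circRNAs held 13 circRNAs of 10 hosts, and 13 of 13 were fitted higher on day 12 than on day 0. Their median log2 fold change was 3.17, or 1.38 with unlisted circRNAs at their bound, against 1.36 and 0.34 over all. The list passed with camera (adjusted p = 0.00203, and 0.00425 with the replicate block), but adjusted p = 0.164 with an estimated correlation. Over all circRNAs 0 of its members passed and 4 passed adjusted over the list alone, the pair of Rmst circRNAs, Tulp4 and Rims2. At day 4 against day 0 the list also passed (median 3.04, or 1.01 with bounds, camera adjusted p = 0.00289, and adjusted p = 0.176 with an estimated correlation), with 1 member past adjusted over the list alone, Rmst. The list was partly drawn from this study's paper and is not independent evidence. At day 12 against day 4 it did not pass (adjusted p = 0.736).

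The other 4 lists did not pass in P19 at day 12 against day 0. Of widely expressed circRNA hosts, 27 of 28 circRNAs were fitted higher (median 1.62, or 0.84 with bounds, adjusted p = 0.146). For hosts of the postsynaptic density and receptors 6 of 6 were fitted higher (median 4.48, or 0.82 with bounds, adjusted p = 0.146). Hosts of chromatin and transcription had 24 higher and 11 lower (adjusted p = 0.745), and for those of the cell cycle (4 higher and 3 lower, adjusted p = 0.92) the median of 3.91 and the test, which pointed down, differed in sign.

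In SH-SY5Y day 4 was compared with day 0 to follow the response to retinoic acid in human cells. The circRNA of ZNF91, a KRAB zinc-finger gene that represses retrotransposons (chromosome 19, 23541232 to 23545527, minus strand, both ends in the gene), rose. It had 0 and 0 reads on day 0, 18 on day 2, 12 and 30 on day 4 and 31 on day 8, at least 18.3-fold higher on day 4 on TMM-scaled totals and 28.6-fold on the list totals (adjusted p = 2.00e-08 by edgeR). It was the only call whose days did not overlap. The call leans on the deep library of day 0: without day 0 replicate 1, which held 9182 reads, the bound fell to 6.78-fold on the list totals and the adjusted p rose to 0.937. With any other library of these days left out it still passed. These values for single calls were added after the data were seen. A junction inside the noncoding gene ENSG00000259001 (chromosome 14, 20811283 to 20811431) fell, at least 8.16-fold on the list totals and 15.3-fold scaled (adjusted p = 1.44e-06), with 60 and 0 reads on day 0, 67 on day 2, and 0 and 0 on day 4. A junction between the tubulin gene TUBB2A and the pseudogene TUBB2BP1, which has a sequence copy, rose at least 7.42-fold scaled and 13.4-fold on the list totals (adjusted p = 0.00148), with 0 and 0 reads on day 0 and 0 and 17 on day 4. These last were chosen after their values were seen, since their days overlapped, and both rest on 1 library. In this fit the spread was drawn wholly from all circRNAs together (infinite prior degrees of freedom against 2 residual ones). Disagreement between a circRNA's own libraries thus carried no weight, so these small p-values do not show that replicates agreed.

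By edgeR 3 of 593 circRNAs passed (2 higher and 1 lower), 19 had an unadjusted p under 0.05 (a mean of 10.9 and at most 18 without any change) and DESeq2 called 0. Without day 0 replicate 1 the count was 0, and without day 4 replicate 2 it was 2. The replicate block gave 4. Days did not overlap for 167 (28.2%), 74 higher and 93 lower, against 27.7% without any change (22.5% to 30.3%). ASAP1, a regulator of Arf GTPases, chosen after its values were seen, went from 8 and 9 reads to 39 and 24 (log2 fold change 2.18, SE 0.61, adjusted p = 0.0556). The list of retinoic acid response, with 46 names in the human annotation, had 4 tested circRNAs of 3 hosts, too few for a list test. All 4 were listed on day 4 but not on day 0, as were 22 of the 593, and 0 passed. Among them CYP26B1, which clears retinoic acid, had 0 and 0 reads on day 0, 9 on day 2 and 9 and 2 on day 4. DHRS3, a retinal reductase, had 0 and 0, then 5, then 4 and 7. Each was at least 4.80-fold above the floor on TMM-scaled totals. On the list totals the bounds were 5.22-fold and 7.15-fold, and 1.24-fold and 1.7-fold without day 0 replicate 1. Their adjusted p by edgeR were 0.682 and 0.856, and each had 0 reads on day 8. The other 2, of the neurotrophin receptor gene NTRK2, each had an adjusted p of 0.996. In P19 the list had 2 tested circRNAs, of Hoxb3 and Nrip1, both listed on day 4 but not on day 0, as were 157 of the 415. Both were fitted higher at day 4 against day 0 and lower at day 12 against day 4, and 0 passed. At day 12 against day 0 Nrip1 was fitted higher and Hoxb3 was unlisted on both days. These tallies were made after the data were seen. The median log2 fold change of all 593 was −0.17, and −0.04 without scaling.

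**Figure D2:**
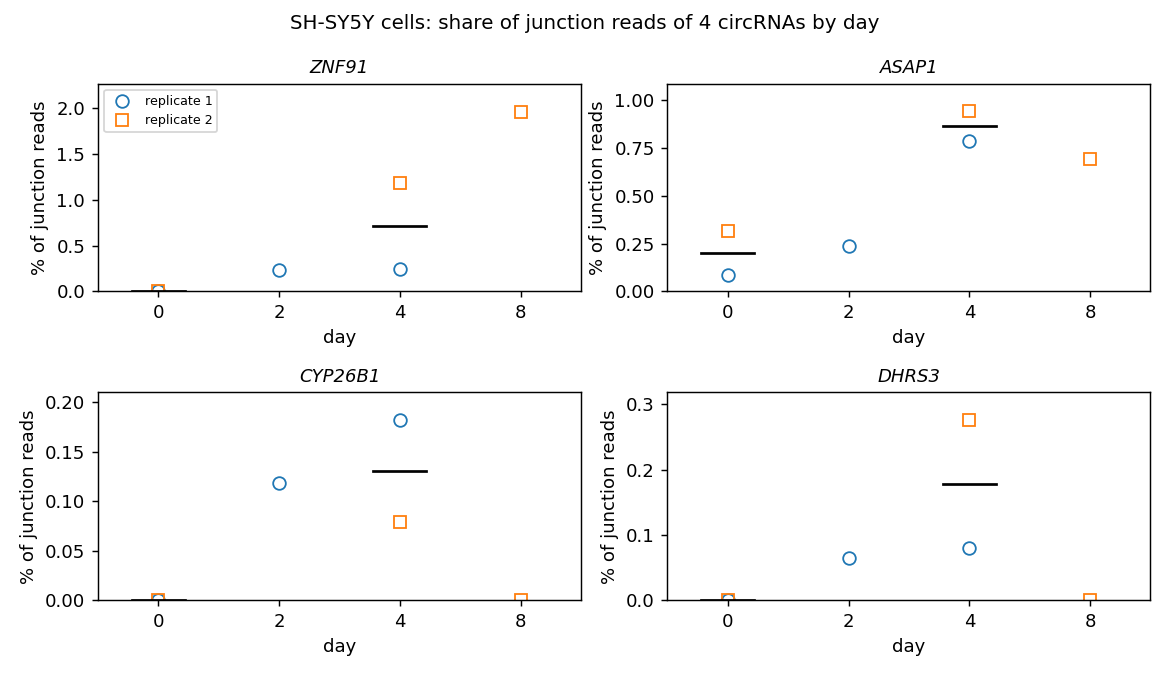
Share of junction reads (%, linear axis) of 4 SH-SY5Y circRNAs by day, 1 point per library, marked by replicate. ZNF91 had 0 reads in both day 0 libraries and 12 and 30 reads on day 4, and ASAP1 went from 8 and 9 reads to 39 and 24.

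The most abundant SH-SY5Y junction joined the tubulin genes TUBA1A and TUBA1B, with 3.27% to 5.04% of reads and a sequence copy. HIPK3 took 0.831 ± 0.113% on day 0 and 0.847 ± 0.028% on day 4 (n = 2 each), and MAN1A2, a mannosidase of the secretory pathway, 0.873 ± 0.202% and 1.03 ± 0.321%. A second junction in ENSG00000259001 took 1.55 ± 0.434% and 1.63 ± 0.48%. EXOC4, which codes for a subunit of the exocyst, took 0.207%, 0.079% and 0.202% on days 0, 2 and 4 of the first experiment and 1.89%, 1.1% and 1.77% on days 0, 4 and 8 of the second. Of the always reported circRNAs KAT6B had the highest log2 fold change (1.76, SE 1.17). For CDR1as, RIMS2, TULP4, HOMER1, ZNF609 and HIPK3 the log2 fold changes were smaller than their SEs. Host lists gave 0 calls among 9 with camera. The lowest adjusted p was 0.0777 for cell adhesion and axon guidance, with 5 of 5 circRNAs fitted lower (median −2.13, or −1.70 with bounds).

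The 4 brain regions were compared to see which circRNAs mark a region, each with the other 3 pooled, over 333 circRNAs. These ratios rest on 1 library per region, and their intervals and floors cover counting error only. Between libraries of the same P19 or SH-SY5Y day such intervals excluded 1 for 54 of 224 circRNAs (24.1%), or 20.2% of those with both ends in 1 gene. The 5 pairs ranged from 8.3% (P19 day 0) to 44.4% (P19 day 12), so this share is a loose guide. Values after "at least" are taken against the floor of 3 counts, with the exact lower limit in brackets. That limit takes an unlisted circRNA as 0 reads, although a list can lack a single read. In the cerebellum Rims2 took 5.73% of all junction reads (817 reads, exact 95% interval 5.35% to 6.12%), against 0.488% in hippocampus, 0.791% in prefrontal cortex and 0.458% in olfactory bulb, a ratio of 9.52 (7.88 to 11.6). The highest ratios were those of a pair of circRNAs from Chd7, a chromatin remodeler. One spanning exons 2 and 3 (chromosome 4, 8678471 to 8712910) had 36 reads against 2, a ratio of 26.4 (6.80 to 227), and one of exon 2 had 43 against 0, at least 21.0-fold higher (16.4). Syne1, a nuclear envelope gene whose loss causes ataxia, had a ratio of 17.6 (4.37 to 154), Cnksr3 at least 14.2 (10.8) and Dbc1 14.0 (3.36 to 124). The interval lay above 1 for 57 circRNAs and below 1 for 97 in the cerebellum, and for 79 and 75 with TMM-scaled totals, which moved the median log2 ratio from −0.35 to −0.08. Together these were 46.2% of the 333.

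In the hippocampus the highest ratios were those of Pvt1, a noncoding gene next to Myc (8.14, 4.10 to 17.1), Mllt3 (6.38, 2.5 to 17.6), Zbtb20, a transcription factor of hippocampal development (5.54, 3.33 to 9.36), Klhl2, an actin-binding ubiquitin ligase adaptor (4.76, 2.67 to 8.58), and the axon guidance receptor Robo1 (4.69, 2.20 to 10.2). In the prefrontal cortex they were those of Satb1, a chromatin organizer of cortical interneurons (14.2, 5.23 to 47.9), 2310046A06Rik (8.28, 3.30 to 23.5), the potassium channel Kcnt2 (7.82, 3.08 to 22.3), Tmem132d (6.44, 2.60 to 17.4) and Arhgap32 (5.56, 2.52 to 12.9). In the olfactory bulb they were those of Auts2 (8.42, 3.48 to 21.2), Rere (5.47, 2.08 to 14.2), Fam184a (4.99, 3.07 to 8.05), Lrba (4.81, 2.06 to 11) and Zmynd11 (4.41, 1.83 to 10.3). The interval lay above 1 and below 1 for 37 and 35 circRNAs in hippocampus, 40 and 41 in prefrontal cortex, and 35 and 37 in olfactory bulb. These were 21.6%, 24.3% and 21.6% of those compared, within the range of the replicate pairs. With TMM-scaled totals these were 26 and 43, 42 and 41, and 19 and 73. With 1 read where a circRNA was not listed the olfactory bulb had 35 and 16. Without the cerebellum in the pool, an alternative chosen after the data were seen, 198 circRNAs were compared and the interval excluded 1 for 23 in hippocampus, 39 in prefrontal cortex and 44 in olfactory bulb. The cerebellum gave 14267 of the 27634 reads pooled against hippocampus and of the 26865 pooled against prefrontal cortex, so low reads there can raise a ratio. Reads in hippocampus, cerebellum, prefrontal cortex and olfactory bulb were 30, 2, 17 and 4 for Klhl2 and 18, 2, 8 and 4 for Robo1. For Zbtb20 they were 41, 7, 6 and 14. All 5 circRNAs named for prefrontal cortex had 0 reads in cerebellum. In the same order of regions the reads were 5, 0, 22 and 0 for Satb1 and 5, 0, 18 and 2 for 2310046A06Rik. Kcnt2 had 7, 0, 17 and 0, Tmem132d 5, 0, 16 and 3, and Arhgap32 3, 0, 19 and 8. Their ratios thus rest in part on the cerebellum.

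**Figure D3:**
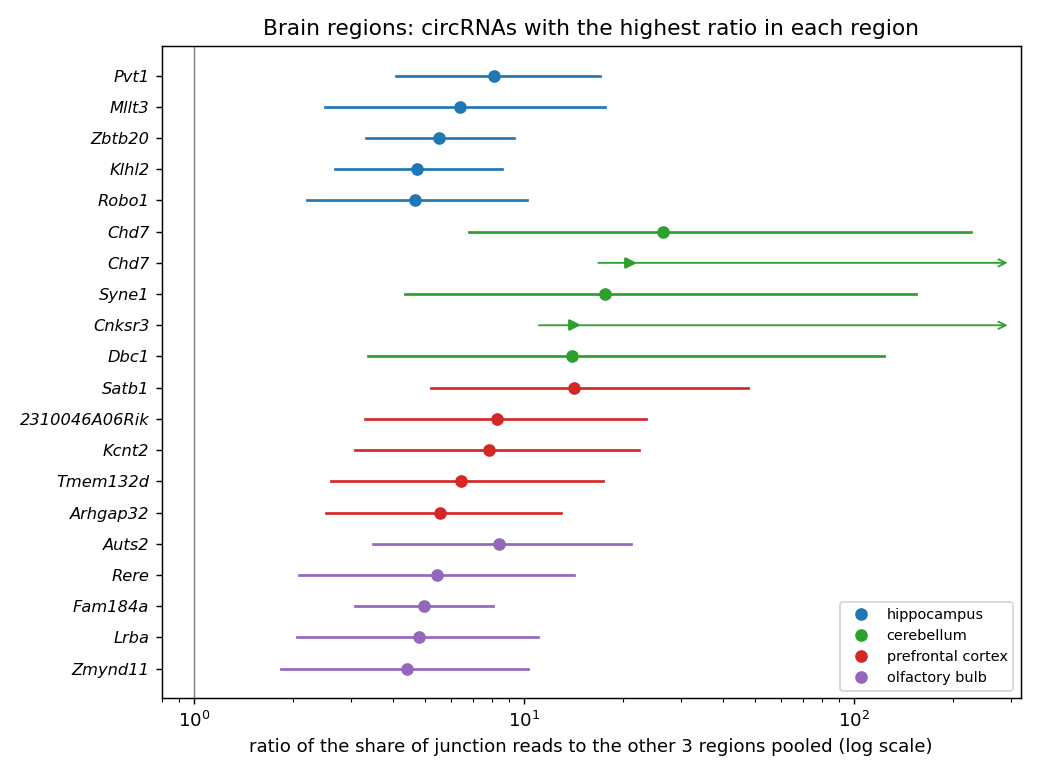
Ratio of the share of junction reads in 1 region to the other 3 regions pooled (log axis) for the 5 circRNAs with the highest ratio in each region, with exact 95% intervals of counting error. Chd7 in cerebellum had ratios of 26.4 and at least 21.0 (exact lower limit 16.4), and Satb1 in prefrontal cortex had 14.2.

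Among the most abundant circRNAs of the regions, Tulp4 took 1.21% of reads in hippocampus, 2.17% in cerebellum, 1.41% in prefrontal cortex and 1.57% in olfactory bulb. Rasa2, a Ras GTPase-activating gene, took 2.01% in olfactory bulb and 0.407% to 0.568% elsewhere. Hnrnpu and Cdyl ranged from 0.502% to 0.956% and from 0.383% to 0.799%. Homer1, a scaffold gene of the postsynaptic density, was highest in prefrontal cortex with 37 reads (2.65, 1.67 to 4.18), where Rmst also lay above 1 (2.58, 1.36 to 4.83). The cerebellum held 81 reads of Elf2 (1.8, 1.29 to 2.53) and only 2 of Klhl2 (0.0576, 0.00679 to 0.219). Reads in hippocampus, cerebellum, prefrontal cortex and olfactory bulb were 38, 86, 45 and 18 for Hipk3, 25, 77, 26 and 37 for Zfp609, 17, 7, 27 and 14 for Kat6b (Myst4), 6, 26, 9 and 6 for Phf21a, and 9, 6, 10 and 7 for Stau2.

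Hosts of the presynaptic release machinery (12 circRNAs of 8 genes) had a median log2 ratio of 0.79 in cerebellum, above 99.91% of random lists. Of these, 6 lay above 1, among them circRNAs of Rims2 and Rims1, and 1 below, Stx6. The same list had medians of −0.63 in hippocampus and −0.77 in olfactory bulb, at the 0.79 and 0.45 percentiles, but with the cerebellum left out of the pool these were −0.25 and −0.50, at the 17.28 and 24.56 percentiles (8 circRNAs). The low values are thus not told apart from the high share in cerebellum. Hosts of forebrain neurons (7 circRNAs) had a median of 1.17 in hippocampus (99.79 percentile), with Zbtb20, Dlgap1 and Ryr2 above 1, and 0.82 without the cerebellum (99.86 percentile), where Ryr2 no longer lay above 1. In cerebellum it was −1.32 (14.04 percentile). Hosts of ion channels and calcium signalling (12 circRNAs) had a median of 0.77 in hippocampus (99.26 percentile), with Slc8a1, Cacna1c, Ryr2 and Prkce above 1, and 0.44 without the cerebellum (90.95 percentile, 7 circRNAs), where only Slc8a1 still lay above 1. For the other lists and regions the percentiles ran from 6.01 to 93.0 with the cerebellum in the pool. Without it, hosts of the postsynaptic density and receptors (8 circRNAs) reached the 2.93 percentile in olfactory bulb (median −0.82) and the 94.63 percentile in hippocampus. Ryr2 belongs both to the list of forebrain neurons and to that of ion channels and calcium signalling.

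**Figure D4:**
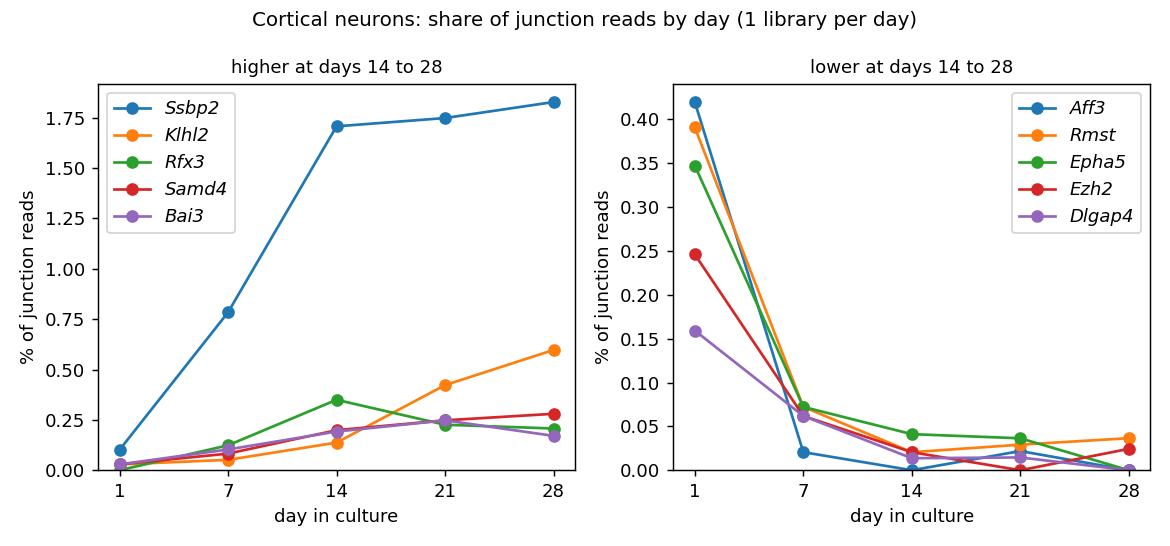
Share of junction reads (%, linear axis) of circRNAs in cortical neurons by day in culture, 1 library per day. Ssbp2 had 7 reads on day 1 and 249 on day 14, while Rmst had 27 on day 1 and 3 on day 14.

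Cortical neurons on days 14, 21 and 28 were pooled and set against day 1 to follow maturation in culture, over 556 circRNAs. Ssbp2, the gene of a single-stranded DNA binding protein (chromosome 13, 91664190 to 91704299, exons 2 to 4), took 0.101% of reads on day 1, 0.784% on day 7, 1.71% on day 14, 1.75% on day 21 and 1.83% on day 28, a ratio of 17.3 (8.33 to 43.1). Klhl2 had 2, 5, 20, 58 and 49 reads (12.0, 3.26 to 100.3), and Rfx3, a transcription factor of ciliated cells, 0, 12, 51, 31 and 17, at least 6.24-fold higher (4.98). Also higher were Samd4 (8.14, 2.19 to 68.3), the adhesion receptor Bai3 (7.19, 1.92 to 60.4) and Dcun1d4 (6.62, 1.77 to 55.8). Lower were Aff3 (chromosome 1, 38591751 to 38593791) with 29 reads on day 1 and 3 in the later libraries (0.0196, 0.00382 to 0.0631), 2610307P16Rik (0.021), a pair of circRNAs of Ezh2, which codes for the methyltransferase of Polycomb complexes (0.0556, 0.0161 to 0.157, and 0.0811), Dlgap4 (0.0688), Rmst (0.0701, 0.0303 to 0.149), Zcchc11 (0.0811) and the ephrin receptor Epha5 (0.0867, 0.0383 to 0.184). The interval lay above 1 for 103 circRNAs and below 1 for 83, for 132 and 71 with TMM-scaled totals, which moved the median log2 ratio from 0.12 to 0.34, and for 59 and 83 with 1 read where a circRNA was not listed. The 103 and 83 were 33.5% of the 556, within the range of the replicate pairs (8.3% to 44.4%).

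A pair of the 8 highest neuron ratios lay in junctions of other kinds. The Scd2 and Scd3 junction, which has a sequence copy, had 180 reads on day 14 and 0 on the other days. A junction on chromosome 2 (98507006 to 98507490, minus strand), which matched no gene, had 0 reads until day 14, 76 on day 21 and 194 on day 28, when it was the most abundant circRNA (2.36%). Around it, between 98490000 and 98520000, junctions took 0.889% of reads on day 21. Junctions near the start of chromosome 9, between 2990000 and 3050000, took 0.495% on day 21 and 3.39% on day 28, and neither stretch had reads on days 1, 7 and 14. Both stretches were chosen after their values were seen. Of the mouse circRNAs without both ends in 1 gene, 15 had ends with 10 or more exact copies in the genome, most of them on chromosome 9, and 0 of those within 1 gene had. The junction on chromosome 2 was not among the 15, since each of its ends occurred 1 time. The search counted exact copies only and asked for them at both ends, so a repeat with mismatches stays open. In the same stretch a junction inside Gm10801 (98503904 to 98504134) had 88 copies of 1 end.

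Hosts of forebrain neurons (6 circRNAs) had a median log2 ratio of 1.18 in neurons (98.75 percentile). Rfx3, Homer1 (3.56, 1.59 to 9.91), Dlgap1 (at least 2.71, exact limit 2.11) and the glutamate receptor Grm5 (at least 1.89, exact limit 1.45) lay above 1, and the transcription factor Zbtb20 (0.274, 0.178 to 0.426) was among those below. The exact limits of Dlgap1 and Grm5 take day 1 as 0 reads, although a list can lack a single read. With 1 read where a circRNA was not listed, the number above 1 among all circRNAs compared fell from 103 to 59. Hosts of chromatin and transcription (29 circRNAs) had a median of −0.45 (2.92 percentile), with 9 below 1, among them Ezh2, Nfix, Tcf20 and Tcf4, and 2 above, Rere and Chd9. Of 14 circRNAs from presynaptic hosts 5 lay above 1 and 0 below (median 0.32, 84.04 percentile), among them Rims1 (3.86, 1.60 to 12.1). For postsynaptic hosts 7 of 26 lay above and 4 below (0.21, 70.68 percentile), and for cell adhesion and axon guidance 6 of 14 above and 5 below (0.29, 56.78 percentile). The list named in work on brain circRNAs had 4 above (Klhl2, Homer1, Dlgap1 and Rims2) and 4 below (Rmst, Elf2, Hipk3 and Tulp4), with a median of −0.42 (18.69 percentile). The Rims2 circRNA of exons 21 to 24 did not share in this (0.865, 0.535 to 1.46). Ion channel hosts had 5 above and 1 below, cytoskeleton hosts 0 and 0, and widely expressed hosts 2 and 8, with percentiles from 10.51 to 62.48.

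Among the most abundant circRNAs of neurons Tulp4 took 2.37% of reads on day 1 and 1.83% on day 28, Magi1, a synaptic scaffold gene, 0.333% and 1.11%, Rasa2 0.666% and 0.865%, and Mboat2 0.926% and 0.5%. From day 1 to day 28 the reads of the other always reported circRNAs were 54, 46, 81, 75 and 58 for Zfp609, 16, 15, 21, 29 and 12 for Kat6b (Myst4), 22, 21, 50, 50 and 25 for Stau2, and 0, 9, 5, 7 and 5 for Phf21a. Single days against day 1 gave 53 circRNAs above 1 and 44 below on day 7, 76 and 63 on day 14, 89 and 72 on day 21, and 84 and 78 on day 28.

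Synaptoneurosomes were compared with cytoplasm to see which circRNAs lie at synapses, over 88 circRNAs. Cdr1as, the circRNA that binds the microRNA miR-7 (X chromosome, 58436423 to 58439349, plus strand, antisense to Cdr1), took 1.01% of reads in synaptoneurosomes (48 reads, exact 95% interval 0.746% to 1.34%), 9.11% in cytoplasm (271 reads, 8.10% to 10.2%) and 5.83% in lysate (200 reads, 5.07% to 6.66%). Its ratio of synaptoneurosomes to cytoplasm was 0.111 (0.0799 to 0.151). Rims2 lay higher in synaptoneurosomes (43 reads against 12, ratio 2.25, 1.16 to 4.68), as did A830093I24Rik (4.70, 1.09 to 42.4), a junction of Ptk2 with 1 annotated end (4.39, 1.01 to 39.8), the neuronal RNA-binding protein gene Elavl3 (at least 2.51, exact limit 1.74), Tmem132d (at least 2.72, exact limit 1.91) and a junction without a gene on chromosome 5 (37573320 to 37585543, at least 3.97, exact limit 2.92). Lower were Spred2 (0.251, 0.0797 to 0.684), Fat3 (0.331, 0.179 to 0.592), Zfp609 (0.436, 0.215 to 0.862), Plcl2 (0.439, 0.205 to 0.913), the sodium-calcium exchanger Slc8a1 (0.47, 0.24 to 0.903), Tulp4 (0.667, 0.464 to 0.959), the noncoding Snhg11 with 0 reads against 13, and a short junction within the Cdr1as locus (0.114, 0.0285 to 0.335). The interval lay above 1 for 6 and below 1 for 9, and for 4 and 14 with TMM-scaled totals, which moved the median log2 ratio from 0.26 to 0.05. The 15 circRNAs were 17% of the 88, within the range of the replicate pairs. With reads of the Cdr1as locus left out of the totals, over 86 circRNAs, it lay above 1 for 4 and below for 9, against 6 and 7 with all reads. A830093I24Rik and Ptk2 no longer lay above 1 in either setting (lower limits 0.944 and 0.87 with TMM-scaled totals, 0.987 and 0.91 without the locus), and Rims2 had a lower limit of 1.005 and 1.05.

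The list named in work on brain circRNAs (13 circRNAs) had a median log2 ratio of 0.78 in synaptoneurosomes over cytoplasm, above 99.86% of random lists, while only Rims2 lay above 1 and Cdr1as, Zfp609 and Tulp4 below. Over the lysate its median was 0.06 (92.3 percentile), with 0 above and 1 below. Because part of this list came from this study's paper, its rank among random lists is not independent evidence. Postsynaptic hosts (5 circRNAs) also had a median of 0.78 (85.55 percentile) with 0 above and 0 below. Chromatin hosts had −0.14 (41.04 percentile) and widely expressed hosts −0.12 (65.06 percentile). Against the lysate, synaptoneurosomes had Mboat2 (3.86, 1.59 to 11.3) and Rasa2 (2.98, 1.35 to 7.47) above 1 and 4 circRNAs below, and cytoplasm had 6 above and 3 below, with Cdr1as at 1.56 (1.30 to 1.89). Reads in lysate, synaptoneurosomes and cytoplasm were 14, 36 and 12 for Hipk3, 13, 16 and 9 for Elf2, 13, 11 and 4 for Homer1, 13, 17 and 8 for Klhl2, 10, 18 and 4 for Rmst, 8, 15 and 5 for Dlgap1, 12, 22 and 8 for Kat6b (Myst4), 9, 13 and 4 for Stau2, and 4, 4 and 2 for Phf21a. Ssbp2 took 1.08%, 0.779% and 0.572% and Magi1 0.787%, 0.969% and 1.14%.

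Cdr1as was also compared between the lysate and the dissected regions. It took 0.185% of reads in hippocampus, 0.449% in cerebellum, 0.324% in prefrontal cortex and 0.179% in olfactory bulb, with 114 reads over the 4 regions. The ratio of the lysate to the regions pooled was 18 (14.2 to 22.9). In cultured neurons it had 4 reads on day 21, 2 on day 28 and 0 on the other days, and human CDR1as had at most 7 reads in an SH-SY5Y library. Lysate and fractions came from NMRI mice and were run on a HiSeq2000, whereas the regions came from C57BL/6 mice and were run on a HiSeq2500, so strain and sequencing cannot be told apart from tissue here.

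**Figure D5:**
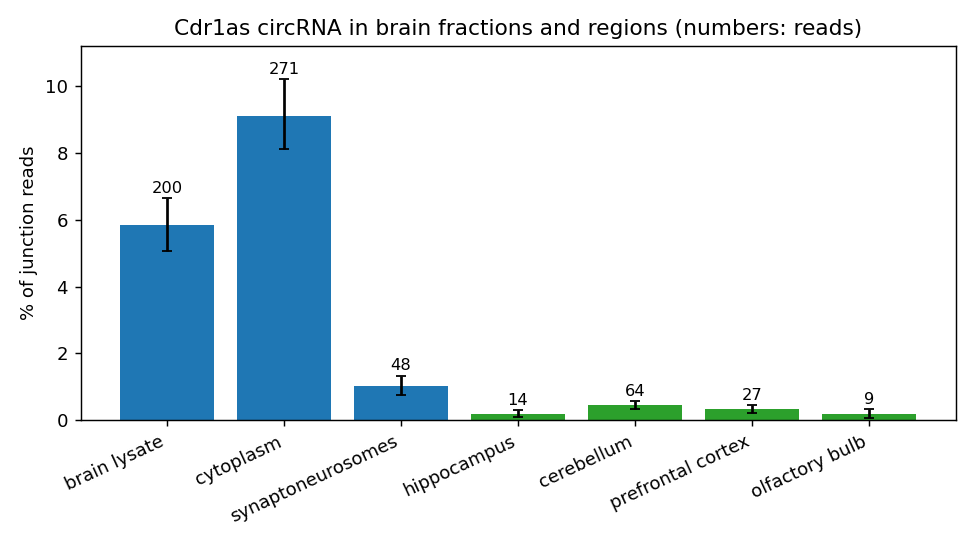
Share of junction reads (%, linear axis from 0) of Cdr1as in brain fractions and regions, 1 library each, with exact 95% intervals of counting error and the reads above each bar. Cytoplasm and lysate stood at 9.11% and 5.83%, synaptoneurosomes at 1.01% and the regions between 0.179% and 0.449%.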

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

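The tests in this part were written down before their results were seen, except the corrected thinning, the thinned ratios by experiment and the shares of single genes by experiment, which were chosen after the data were seen. The number of circRNAs listed as deposited moved in opposite directions in the 2 cell lines between day 0 and day 4 of retinoic acid. In P19 the ratio of day 4 to day 0 was 1.30 for replicate 1, assumed to be a first experiment, and 3.75 for replicate 2, and in SH-SY5Y it was 0.600 and 0.931. Each P19 ratio thus went up and each SH-SY5Y ratio down, but the difference between the lines was not tested. The contrast was lost at equal reads. After thinning the ratios were 0.904 and 0.833 in P19 and 1.16 and 1.04 in SH-SY5Y, and after the corrected thinning they were 0.986 and 1.17 in P19 and 0.991 and 1.01 in SH-SY5Y. Of the genes of the always reported circRNAs, 4 could be compared between the lines (Rims2, Tulp4, Zfp609 and Hipk3), and none of their shares rose in both experiments of one line and fell in both of the other. The most abundant circRNA of each gene was taken, matched between species by gene symbol alone. For Rims2 it ran from 39398489 to 39448056 in mouse but from 104897526 to 104898451 in human. These spans differ widely, so that pair need not be the same circle. The fitted log2 fold changes of day 4 against day 0 in P19 and SH-SY5Y differed in sign for Zfp609 (0.70 and −0.03) and Hipk3 (1.21 and −0.16), which was not tested. Libraries simulated without any change had medians of 0.94 in P19 and −0.28 in SH-SY5Y, so opposite signs can arise without a change. The SH-SY5Y values were also smaller than their SEs (0.58 and 0.50). On the list totals the P19 log2 ratios were 0.13 and 0.78.

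Junctions whose ends lie in 2 genes, such as those of Tubg1 and Tubg2, Scd2 and Scd3, or TUBA1A and TUBA1B, were examined for sequence copies. Of these junctions 75.0% had a copy from which linear splicing within 1 gene would give the same join, against 0.098% of circRNAs within 1 gene. Reads of linear RNA from near-identical gene copies are thus a candidate explanation for most of them. True circles or RNAs joined between genes stay open for each single junction.

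P19 circRNAs were fitted higher on day 12 than on day 0 in the median, with a log2 fold change of 1.36. When all P19 libraries were thinned, until the reads of circRNAs with 2 or more came to the smallest total of 1222, the median over 20 draws came to 0.03 (0.0339, range −0.18 to 0.25). Fewer reads on day 0, together with the minimum of 2 reads for a listed circRNA, may account for most of that shift. The thinned draws held a mean of 178.2 tested circRNAs in place of 415, so the drop also takes in a change of the circRNAs compared. Those listed on both days had a median of 0.32 without thinning. Simulated libraries without any change gave a median of 1.09 with TMM (0.85 to 1.27 over 20 runs) and 0.28 without scaling. Most of the simulated shift thus came in through the scaling, and the observed 1.36 lay above all 20 runs. Without scaling the observed median was 0.71. A general rise of circRNAs in differentiation stays open, since shares of junction reads cannot show one.

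Cdr1as took a share of reads 18-fold larger in brain lysate than in the dissected regions. Reads listed under neighbouring junctions in the regions were argued against, as the ratio of the whole locus was 17.8 (14.3 to 22.3). For a difference of strain or library preparation that moves abundant circRNAs alike, the 50 most abundant others were examined. They had a median absolute log2 ratio of 0.44 (0.36 to 0.75) against 4.17 for Cdr1as, the outcome written down beforehand for no such cause. A shift common to most circRNAs would cancel in shares of the total, so this test cannot decide. It shows only that these others moved less than Cdr1as relative to the total. A difference particular to Cdr1as, whether of strain, of the brain parts sampled or of the preparation, may remain and cannot be told apart here, because each came with 1 library and another mouse strain and sequencer.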

How the results depend on the processing

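Alternatives were fixed before the data were examined, except those with only both ends in 1 gene, without sequence copies, with the replicate block for gene lists, with the corrected thinning and without the cerebellum, which were chosen after seeing the data. For the results that answer a comparison 100 alternative values stayed the same, 51 moved and 8 reversed. For single circRNAs 589 stayed the same, 23 passed the threshold where the main analysis did not, 5 moved and 32 reversed. Where a result changed, the cause was not tested, except that higher minimum counts, thinning and leaving out a region leave fewer circRNAs by construction. Libraries of 1222 to 14588 junction reads limit every count.

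The number of circRNAs passing in P19 at day 12 against day 0, 0 by edgeR with TMM, was 4 with RLE, 17 without scaling, 1 with TMMwsp, 8 with DESeq2, 9 without a filter, 6 with at least 5 reads, 15 with 1 read where not listed, 2 with only the libraries of both days, 9 with the replicate block, 4 summed per host gene and 3 with only both ends in 1 gene. Leaving out 1 library at a time gave 0 to 0, the lone library being assumed to vary like the other groups. At day 4 against day 0 the count was 1 with RLE, 2 without scaling, 1 with TMMwsp, 2 with DESeq2, 6 without a filter, 1 with at least 5 reads, 2 with 1 read where not listed, 1 with only the libraries of both days, 3 with the replicate block, 3 summed per host gene and 0 to 1 leaving out a library. At day 12 against day 4 it was 7 without scaling, 7 without a filter, 2 with 1 read where not listed, 5 with the replicate block and 0 to 0 leaving out a library. In SH-SY5Y the count of 3 became 0 with DESeq2 and 0 to 3 leaving out a library. Gene lists passing at day 12 against day 0 numbered 1 with camera, 0 with an estimated correlation and 3 with fry, which tests against 0 where the median without any change was already 1.09, and at day 4 against day 0 there were 0 with an estimated correlation.

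With at least 50 reads the circRNAs whose interval excluded 1 numbered 30 in hippocampus, 60 in cerebellum, 40 in prefrontal cortex, 26 in olfactory bulb, 79 in neurons and 6 in synaptoneurosomes against cytoplasm. Without the cerebellum they numbered 23 in hippocampus, 39 in prefrontal cortex and 44 in olfactory bulb. The ratio of circRNAs listed became 0.814 for P19 when thinned and 1.09 with the corrected thinning, 1.09 and 1.00 for SH-SY5Y (0.466 to 1.31 leaving out a library), 0.926 and 1.04 for neurons, 0.749 and 0.875 for cerebellum over olfactory bulb, and 0.99 for synaptoneurosomes over cytoplasm when thinned. CircRNAs in every library numbered 11 in P19, 70 in fractions, 144 in neurons, 128 in regions and 34 in SH-SY5Y with at least 5 reads, and 20.8 in P19, 221.9 in regions and 38.8 in SH-SY5Y when thinned.

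Reversed log2 fold changes of single circRNAs, none past the threshold, were as follows. In P19, Stau2 at day 4 against day 0 had −0.058 with 1 read where not listed. At day 12 against day 4 Hipk3 had 0.0005 with DESeq2, and leaving out a library gave −0.49 to 0.86 for Rmst, −0.56 to 0.61 for Elf2, −1.58 to 0.034 for Phf21a, 0.33 to 0.33 (0.325) for Homer1, −0.22 to 0.61 for Zfp609 and −0.35 to 0.20 for Hipk3. In SH-SY5Y, CDR1as had −0.055 with RLE, −0.068 with TMMwsp, −0.068 with DESeq2, −0.21 without a filter, −0.051 with at least 5 reads, −0.066 with only the libraries of both days and −0.50 with the replicate block. HOMER1 had 0.19 without scaling, 0.071 with TMMwsp, 0.12 with DESeq2, 0.054 with only the libraries of both days and 0.37 with the replicate block, and ZNF609 had 0.032 without sequence copies. Leaving out a library gave −0.97 to 1.11 for CDR1as, −0.83 to 0.95 for RIMS2, −0.21 to 0.91 for TULP4, −0.75 to 4.65 for HOMER1, −0.62 to 0.68 for ZNF609 and −0.38 to 0.088 for HIPK3.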

Other observations

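The observations in this part were all chosen after their values were seen. The single P19 library of day 2 entered no comparison. In it Mdk, the gene of the growth factor midkine, had 17 reads, against 2 and 0 on day 0, 9 and 11 on day 4, and 0 and 0 on day 12, at a junction with 1 annotated end. Mboat2, an acyltransferase gene, had 11 reads on day 2, 4 and 0 on day 0, and 22 and 18 on day 12. Ptbp2, which codes for a neuronal splicing regulator, had 19 reads on day 2, 23 and 22 on day 0, 25 and 34 on day 4, and 43 and 31 on day 12. Crebbp, the gene of a histone acetyltransferase, had 19 reads on day 2, 48 and 25 on day 0, and 29 and 7 on day 12.

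In the single SH-SY5Y library of day 8 ZNF91 had 31 reads, beside 18 for HIPK3, 16 for ZNF609, 14 for RHOBTB3 and 11 for LPAR1, a receptor of lysophosphatidic acid. On day 2 these had 18, 51, 15, 32 and 14 reads. These values have no replicate.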
